A study of Homo sapiens with 12 samples.

How the data were processed

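The values analysed were FPKM, fragments scaled to transcript length and library total, in 2 tables deposited by the authors, 1 for EtOH and 1 for DHT. The tables do not name the unit, which was inferred from their layout and values. The submitters' processing notes name TopHat and the GRCh37 build, without a version. The quantifier, gene annotation, filters, DHT dose and sequencing depth are not given in the sources used here. The labels describe TruSeq stranded total RNA libraries, although their molecule field says genomic DNA. The titles of 2 libraries name D226G with DHT while their descriptions name M253K with DHT, and they make up the whole M253K DHT group. They were assigned by description, in keeping with the column names of the DHT table.

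Each table holds 1 value per gene row and group, so the 2 libraries of a group had been combined and no spread between replicates could be estimated. The tests fixed before the data were examined, count models and gene set tests over 12 libraries, could therefore not be run, and no p-value is given. Differences were taken on log2(FPKM + 1) and described by size, with a threshold of 2-fold. The size threshold, the rule on repetition and the matched random lists used for percentiles were chosen after the tables were seen. The gene lists, the named androgen genes and the comparisons were fixed before the data were examined.

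Names were matched between the tables: 22518 in the EtOH table, 22408 in the DHT table and 22192 in both. Names on 1 row of both tables with all 6 values numbered 21245, of which 19762 held no small RNA. Small RNA names were recognised from RefSeq tables of the GRCh38 build, and no coordinates were used, since the tables' build is GRCh37. Names with a mean of at least 0.5 FPKM over the 6 groups were compared between hormones (11480). Within a hormone condition the mean was taken over its own groups. Small RNAs held 50.5% to 60.2% of the summed values of a group. Values were used as deposited. Whether the 6 columns were normalized together is not stated, and median-ratio factors lay between 0.985 and 1.02.

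The named genes were FOXA1, KLK3, KLK2, TMPRSS2, FKBP5, UGT2B15 and UGT2B17 in every comparison, the 6 largest differences in each direction among names with a mean of at least 8 FPKM, and up to 3 members past 2-fold from each list. Some genes that this rule selects are not reported here. The rule asked for adjusted p-values and separation of replicates, which do not exist here. In their place a largest difference had to pass 2-fold and to reach 1.5-fold in the same direction in the other hormone condition, or, for DHT, in the other FOXA1 forms. The median difference of each of 19 lists was placed among 10000 random lists matched on mean expression in 20 bins, where at least 5 members were measured. Of 144 list medians, 63 lay outside percentiles 2.5 to 97.5, where independent unchanged genes would give 5%. Members of a list are regulated together, so the percentiles overstate how unusual a list is.

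The steps were tested on simulated data with a spread of 0.124 per group on the log2 scale, taken from the interquartile width of the differences between the mutants under EtOH and not from replicates. That is the narrowest comparison, and M253K against WT under DHT had an interquartile width of 0.359, so the simulation understates the spread there. Over 11480 simulated names, 50 genes were planted at each fold, all of them among names with a mean of at least 8 FPKM. Recovery at lower levels, where the pseudocount of 1 shrinks differences, was not simulated. The recovery below therefore does not hold for the whole 2-fold count. In M253K against WT under DHT the 2-fold count recovered 0 at 1.5-fold, 23 at 2-fold and 49 at 3-fold. The repeat rule, set at 1.5-fold and run on both mutants against WT in both hormone conditions, recovered 3, 46 and 50, so it misses most differences of its own size. Neither called an unchanged gene. That simulation gave every gene the same spread and held no genes listed near 0 in single groups, so false calls in the real tables are not bounded by it. The repeat rule was used on 6444 of the real names. Of 100 unchanged lists, also drawn from names with a mean of at least 8 FPKM, 5 fell outside percentiles 2.5 to 97.5. Versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.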

Results

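RNA was sequenced from LNCaP cells, an androgen-responsive human prostate cancer line, carrying a doxycycline-inducible V5-tagged FOXA1. FOXA1 is a pioneer transcription factor that opens chromatin through its forkhead DNA-binding domain. The construct was wild type (WT) or 1 of 2 forkhead-domain missense mutants, D226G and M253K. After 2 days of doxycycline in medium with 5% charcoal-stripped serum, cells received dihydrotestosterone (DHT, the most potent natural androgen) or ethanol (EtOH, its vehicle) for 16 h. The 12 libraries form 6 groups of 2, and the labels call the replicates technical. The M253K DHT group consists of 2 libraries whose titles name D226G and whose descriptions name M253K, and the values used for it are those the DHT table names M253K. The deposited tables hold 1 combined FPKM value per gene row and group, so no comparison has a replicate check: every value stands without an error, and no difference was tested. A difference is therefore described by its size, and by whether it recurred in the other hormone condition or in the other FOXA1 forms. Total depth is unknown. The most frequent ratio of low values to those of the WT EtOH group ran from 0.849 in the M253K EtOH group to 1.02 in the D226G EtOH group. No uninduced line was analysed here, so each comparison is with WT FOXA1 overexpression.

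FOXA1 itself was listed at 348 FPKM in WT cells, 458 in D226G cells and 473 in M253K cells under EtOH. Under DHT the values were 296, 408 and 474. The mutant lines thus held 1.32 to 1.60 times the WT level of FOXA1 mRNA, in which endogenous and introduced transcripts are not separated.

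The effect of DHT in cells with WT FOXA1 was the textbook androgen programme. KLK3, which encodes prostate-specific antigen, was 3.45 times higher with DHT (1153 to 3978 FPKM), and its neighbour KLK2 6.35 times higher (52.6 to 334). The serine protease gene TMPRSS2 was 5.14 times higher (132 to 679). FKBP5, a co-chaperone of steroid receptors listed jointly with LOC285847, was 13.5 times higher (10.1 to 136). The metalloreductase gene STEAP4 was listed at 0 under EtOH and at 15.1 FPKM under DHT, and CENPN, a centromere protein gene, went from 20.8 to 163. Other large differences that recurred in both mutant lines were in NCAPD3, a condensin II subunit (12.1 to 249 FPKM), MRPL42 of the mitochondrial ribosome (16.1 to 193), DCUN1D5 (2.21 to 33.4), CEP41 (5.15 to 77.2) and NAA38 (1.47 to 208). NAA38 was already at 36.7 FPKM in M253K cells under EtOH.

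Genes lower with DHT in WT cells included METTL21A (34.5 to 2.21 FPKM), FAM198B (25.6 to 3.21), the metallothionein gene MT1G (568 to 102) and DDC, which encodes dopa decarboxylase (85.1 to 15.3). LRRN1 went from 15.0 to 2.26 FPKM and BCHE, which encodes butyrylcholinesterase, from 35.1 to 6.70. The kappa opioid receptor gene OPRK1 went from 10.7 to 0.728, and the chemokine receptor gene CXCR7 from 73.5 to 24.6. UGT2B15 and UGT2B17, near-identical glucuronidation genes, were listed jointly at 16.8 FPKM under EtOH and 3.38 under DHT in WT cells. Their rows were split differently between groups, so these values are uncertain: the D226G group had UGT2B17 alone at 16.3 FPKM under EtOH. The same joint rows stood at 19.9 FPKM under EtOH and 4.55 under DHT in M253K cells, and at 4.15 under DHT in D226G cells.

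Gene lists fixed beforehand moved with DHT in WT cells as follows. Of 30 measured androgen-induced genes, 25 were at least 2-fold higher and 0 lower, with a median log2 difference of 1.99, above all of 10000 random lists matched on expression (percentile 100). Of 6 measured androgen-repressed genes, 4 were at least 2-fold lower and 1, UGT2B28, was higher (0.150 to 1.78 FPKM). Of the 22 sterol and fatty acid synthesis genes, 4 were at least 2-fold higher and 21 lay above 0. The median was 0.62 (percentile 100), with MVD of the mevalonate pathway from 9.35 to 26.9 FPKM and the fatty acid synthase gene FASN from 159 to 373. MVD was low in the WT EtOH group alone, and went from 22.2 to 33.5 in D226G cells and from 24.6 to 31.3 in M253K cells. The G1/S replication list had a median of 0.30 (percentile 99.99), with 18 of 19 members above 0, among them UHRF1 (1.53 to 9.41 FPKM), RRM2 (4.41 to 10.8) and E2F1 (6.01 to 13.2). The G2/M list had a median of 0.35 (percentile 100). Its member TOP2A, the mitotic topoisomerase gene, went the other way, at 37.7 FPKM in the WT EtOH group against 6.83 to 7.84 in every other group. The unfolded protein response list had a median of 0.35 (percentile 100) and the UGT2B and steroid metabolism list 0.49 (percentile 99.97). The latter had 7 measured members, 4 above 0 and 3 below, with UGT2B28 the only one past 2-fold. It left out UGT2B15 and UGT2B17, whose joint name is on several rows, as did the androgen-repressed list. The immediate early list had a median of −0.33 (percentile 0.34), while its member NR4A1 was higher (5.89 to 12.9 FPKM).

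In the luminal epithelial list, the median was 0.09 (percentile 95.03), but SPDEF (66.7 to 163 FPKM) and the luminal keratins KRT8 (223 to 506) and KRT18 (307 to 635) were at least 2-fold higher. The remaining lists stayed within the middle 95% of random lists: neuroendocrine (median 0.03), mesenchymal and EMT (−0.14), WNT targets (−0.18), gastrointestinal and liver lineage (−0.25), interferon response (−0.16), hypoxia and glycolysis (−0.04) and ribosomal proteins (−0.14). Single members past 2-fold in these lists were NTS (4.17 to 0.634 FPKM), SNAI2 (0.0685 to 2.51), AGR2 (1.51 to 8.06) and BNIP3 (135 to 295). The basal list had 4 measured members, none past 2-fold. The list of other cell types had 1, the endothelial gene VWF, at 3.49 and 2.66 FPKM. The mitochondrially encoded list had 0 measured members, so it gives no sign of RNA quality.

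In all, 550 of 11480 gene names differed at least 2-fold between DHT and EtOH in WT cells, 318 higher and 232 lower. D226G cells had 472 (305 higher and 167 lower) and M253K cells 542 (280 higher and 262 lower). Among 6444 names with a mean of at least 8 FPKM, 91 were at least 2-fold higher with DHT in all 3 FOXA1 forms and 21 were lower. These levels are set across 2 tables whose joint normalization is not stated, so each also compares tables. Recurrence of a DHT difference in the other forms repeats that comparison, so it does not separate DHT from a difference between the tables. With a pseudocount of 0.1 instead of 1, the 3 counts became 934, 776 and 865, and the majority turned to lower in WT (456 higher and 478 lower) and M253K cells (406 and 459).

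**Figure D1:**
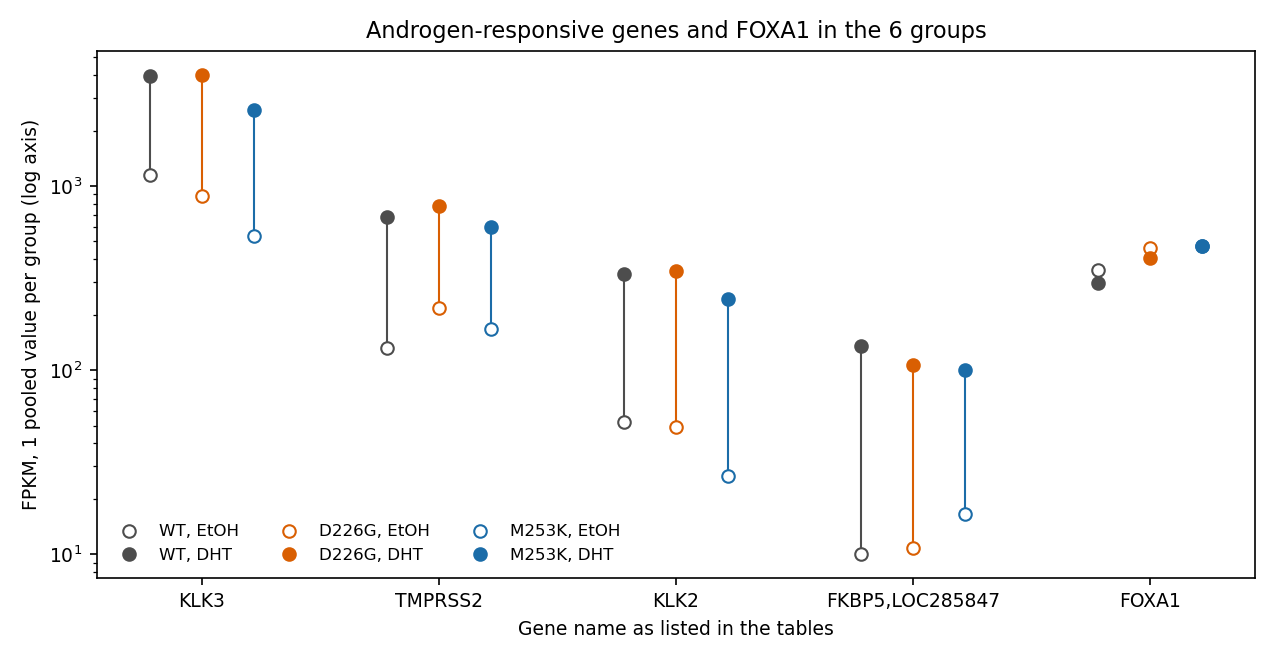
FPKM on a log axis for 4 androgen-responsive genes and FOXA1, with 1 pooled value per group; open circles are EtOH, filled circles DHT, and colours the FOXA1 form. KLK3 spans 538 FPKM in M253K cells under EtOH to 4022 in D226G cells under DHT, while FOXA1 stays between 296 and 474.

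The androgen programme was also present in both mutant lines. KLK3 was 4.56 times higher with DHT in D226G cells and 4.83 times higher in M253K cells. KLK2 was 6.98 and 9.18 times higher, TMPRSS2 3.57 and 3.59 times, and FKBP5 9.86 and 6.07 times. Of the 30 androgen-induced genes, 24 were at least 2-fold higher with DHT in D226G cells (median 1.66) and 25 in M253K cells (median 1.60), both at percentile 100. In M253K cells 1 member, MPHOSPH9, was at least 2-fold lower (275 to 41.8 FPKM). The sterol and fatty acid list had medians of 0.59 and 0.57, also at percentile 100. Of its genes, FASN reached 2-fold in M253K cells (178 to 451 FPKM) and stayed below it in D226G cells (227 to 359). The hypoxia and glycolysis list had a median of 0.35 (percentile 100) in M253K cells, led by ENO1 (197 to 1281 FPKM) and PFKFB4 (3.98 to 18.5). Both genes were lower in the M253K EtOH group than in every other group. CLDN3, a tight junction gene, had the same profile, at 5.17 FPKM there and at 41.7 to 63.6 elsewhere.

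D226G and WT cells were first compared under EtOH, where mutant effects are seen without added androgen. LBH, a transcription cofactor gene, was at 8.94 FPKM in D226G cells against 0.861 in WT cells, and AGR2, a protein disulfide isomerase gene, at 7.31 against 1.51. Also higher were MAFK (14.5 against 4.11), DCUN1D4 (21.5 against 6.21) and 2 names with near-identical relatives, NBPF1 (36.3 against 10.4) and the joint row of FAM45A and FAM45B (35.5 against 7.67). Lower in D226G cells were the netrin receptor gene UNC5B (5.78 against 34.6), the sialyltransferase gene ST6GALNAC1 (0.393 against 15.8), the noncoding transcript IPW (5.80 against 154), SLC38A9 (4.72 against 41.4), CSMD1 (7.58 against 36.0) and LOC100505894 (1.41 against 11.3). IPW and SLC38A9 had a mixed profile: both were also low in M253K cells under EtOH, but not under DHT. CSMD1 and the FAM45A and FAM45B row were mixed too. Their D226G values were near those of the DHT groups, WT included (3.88 to 7.01 and 24.8 to 38.9 FPKM). M253K cells under EtOH held 39.8 and 4.96. Of the androgen genes, KLK3 was at 0.766 of the WT level, TMPRSS2 at 1.65, KLK2 at 0.937 and FKBP5 at 1.07.

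By list, D226G cells under EtOH had a lower median of luminal epithelial genes (−0.23, 10 of 15 below 0 and 0 past 2-fold, percentile 0.02). Their medians were higher for hypoxia and glycolysis (0.32, 13 of 14 members above 0), immediate early genes (0.29, 10 of 12), G2/M (0.18, 22 of 26), sterol and fatty acid synthesis (0.18, 14 of 22) and ribosomal proteins (0.24, 25 of 26), all at percentile 99.9 or above. The neuroendocrine list had a median of −0.27 (percentile 2.5). The interferon response list had no stable direction: its median was 0.15 (percentile 98.1), and −0.0023 with a filter at a mean of 5 FPKM. The androgen-induced list was near 0 (median −0.05, percentile 8.82), with MAF at 1.65 against 4.35 FPKM and MPHOSPH9 at 12.6 against 70.0. Members past 2-fold in other lists were TOP2A (6.85 against 37.7, against the direction of its G2/M list), TFF1, a trefoil peptide gene (13.8 against 38.7), OAS1 (2.49 against 0.491), MVD (22.2 against 9.35), the apolipoprotein gene APOA1 and VWF (0.893 against 3.49). In all, 324 of 11560 names differed at least 2-fold, 113 higher and 211 lower. With a pseudocount of 0.1 there were 554.

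Under EtOH, 48 of 11480 names were at least 2-fold higher and 114 lower than WT in both mutants, which were set against the same WT group. M253K cells were then compared with WT cells. LBH was at 14.2 FPKM against 0.861 in WT cells, AGR2 at 17.5 against 1.51, and APLN, which encodes the peptide hormone apelin, at 55.7 against 11.0. Also higher were the deacetylase gene HDAC2 (75.3 against 10.6), CCNDBP1 (93.2 against 21.9) and MMD (18.0 against 4.09). In D226G cells under EtOH these genes were at 11.4, 22.2 and 5.51 FPKM, so none was 2-fold from WT there. HDAC2 and CCNDBP1 had a mixed profile: the DHT groups, WT included, held 51.0 to 107 and 55.4 to 89.4 FPKM. The genes lower in M253K cells were UNC5B (8.32 against 34.6 FPKM), ST6GALNAC1 (0.569 against 15.8), TFF1 (9.81 against 38.7), UBR2 (7.77 against 27.8), PPPDE2 (16.2 against 50.7) and FXYD3 (22.9 against 64.3). The androgen genes KLK3 and KLK2 were at 0.466 and 0.506 of the WT level, while TMPRSS2 was at 1.26 and FKBP5 at 1.65.

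In M253K cells under EtOH, 13 of 14 hypoxia and glycolysis genes were below the WT level (median −0.46, percentile 0), the opposite side from D226G cells. ENO1 was at 197 FPKM against 1021, PFKFB4 at 3.98 against 27.0 and VEGFA at 55.3 against 104. Luminal epithelial genes were lower (median −0.20, 13 of 15 below 0, percentile 0.14). The G1/S list was higher (median 0.20, percentile 99.75), with UHRF1 at 7.85 against 1.53 FPKM, as were G2/M (0.23, percentile 100) and ribosomal proteins (0.18, percentile 99.9). The ribosomal protein gene RPL37, listed jointly with LOC100506548, was at 1936 FPKM in this group and at 300 to 519 in every other group, and was the only member past 2-fold. The interferon response list had a median of 0.22 (percentile 99.2), but −0.0413 with a filter at a mean of 5 FPKM. Its member OAS1 was at 2.40 against 0.491 FPKM. The androgen-induced list as a whole was near 0 (median 0.01, percentile 25.1) although KLK3 was lower. Other members past 2-fold were TOP2A (6.83 against 37.7), MPHOSPH9 (275 against 70.0), CLDN3 (5.17 against 41.7), DUSP1 (22.0 against 47.7), ITGA6 (12.9 against 5.31) and MVD (24.6 against 9.35). In all, 389 of 11560 names differed at least 2-fold, 205 higher and 184 lower. With a pseudocount of 0.1 there were 627.

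Under DHT, D226G cells again had more LBH (11.5 against 1.23 FPKM) and APLN (132 against 13.7), and more of the neuropeptide gene NMB (39.5 against 13.3), NBPF1 (24.1 against 7.40), DCUN1D4 (15.9 against 5.03) and TMEM68 (18.1 against 6.27). They had less UNC5B (3.54 against 27.9), TFF1 (10.5 against 29.2), SLC38A9 (4.403 against 26.8), IPW (5.38 against 39.6), KIAA1715 (5.16 against 22.0) and AIDA (10.5 against 29.3). KIAA1715 shared the mixed profile of IPW and SLC38A9, at 4.20 FPKM in M253K cells under EtOH and 23.7 under DHT. KLK3 was at 4022 against 3978 FPKM. KLK2 was at 1.03 of the WT level, TMPRSS2 at 1.15 and FKBP5 at 0.783. Even so, 25 of 30 androgen-induced genes were below WT (median −0.24, percentile 0), with NNMT at 1.33 against 4.78 FPKM the only member past 2-fold. Hypoxia and glycolysis genes were again higher, 14 of 14 (median 0.38, percentile 100), with EGLN3 at 12.6 against 5.27 FPKM. Immediate early genes were also higher, 11 of 12 (median 0.32, percentile 99.96). The luminal epithelial list was not lower here (median 0.05, 10 of 16 above 0, percentile 20.35). The stress gene DDIT3 was at 146 against 63.9 FPKM and VWF at 0.681 against 2.66. Ribosomal protein genes, a measure of library composition, had the largest list median of this comparison, 0.45 (percentile 100), with RPS6 at 3952 against 1860 FPKM. In all, 241 of 11353 names differed at least 2-fold, 108 higher and 133 lower. A pseudocount of 0.1 gave 483. Inclusion of small RNAs gave 415 (213 higher and 202 lower), and names on several rows at their largest value 384 (117 and 267), so the balance of directions depends on which rows are used.

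Under DHT, M253K cells had more APLN (143 against 13.7 FPKM), LBH (16.5 against 1.23), C11orf92 (66.1 against 23.0), BAMBI, a decoy receptor of TGF-beta signalling (34.9 against 13.3), S100P (291 against 118) and the chaperone gene CLU, or clusterin (20.5 against 7.89). They had less TFF1 (2.38 against 29.2), UNC5B (6.39 against 27.9), FXYD3 (31.8 against 79.0), MAP1B (25.1 against 59.4), NUCB2 (26.5 against 59.9) and BCAS4 (7.89 against 18.5). KLK3 was at 0.653, KLK2 at 0.732, FKBP5 at 0.743 and TMPRSS2 at 0.880 of the WT level. Of 30 androgen-induced genes, 24 were below WT (median −0.38, percentile 0). EAF2 (3.31 against 9.21 FPKM), STEAP4 (5.81 against 15.1) and NNMT (1.81 against 4.78) were past 2-fold, as was VWF of the other cell types list (0.773 against 2.66). Luminal epithelial genes were lower (median −0.21, 12 of 16 below 0, percentile 0.04), as were hypoxia and glycolysis genes (−0.20, percentile 0.58) and the unfolded protein response list (−0.14, percentile 1.31). Higher medians were seen for WNT targets (0.24, percentile 98.8), interferon response (0.23, percentile 99.0) and G1/S (0.16, percentile 98.2). In all, 99 of 11353 names differed at least 2-fold, 36 higher and 63 lower. The count was 318 with a pseudocount of 0.1, 43 with a filter at a mean of 5 FPKM and 266 with small RNAs, where the majority turned to higher (147 higher and 119 lower).

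**Figure D2:**
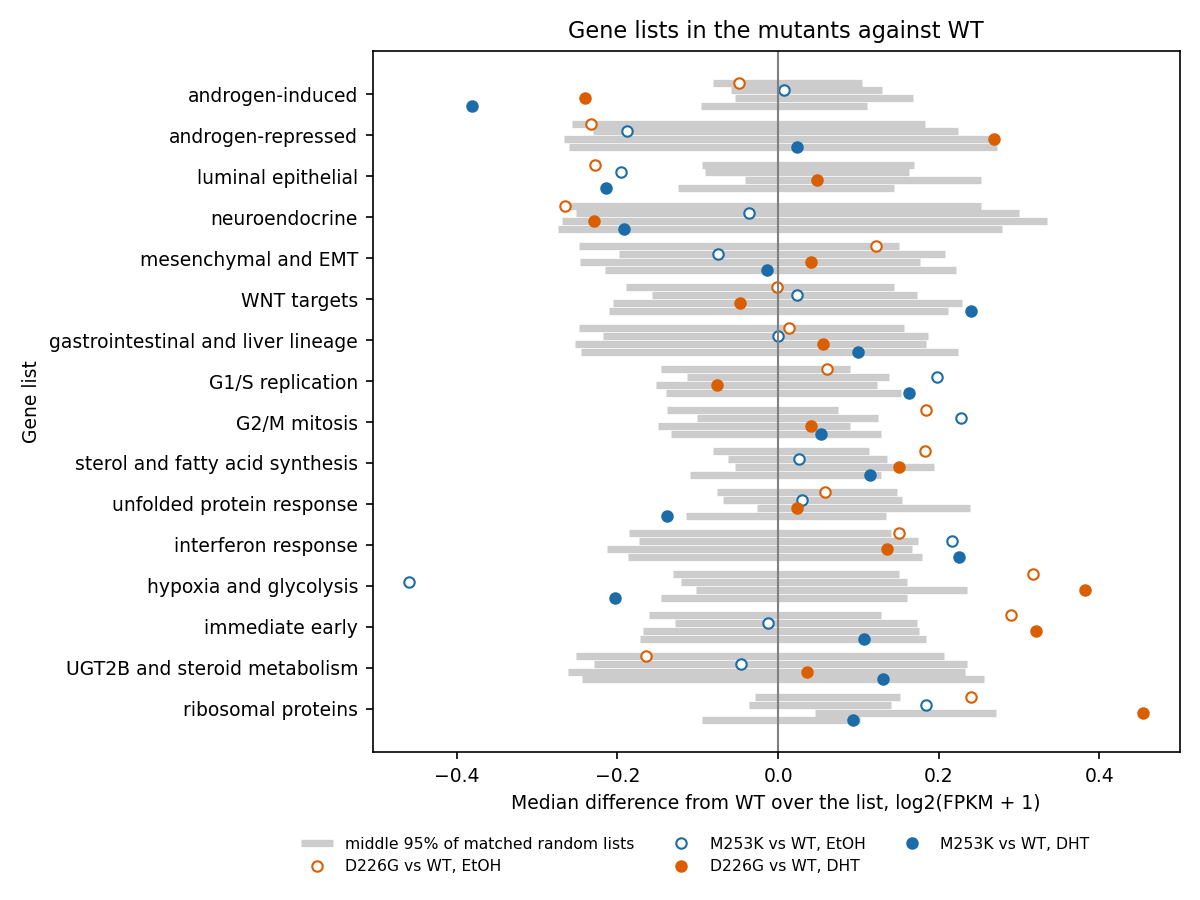
Median log2(FPKM + 1) difference from WT for each gene list, with open circles for EtOH, filled circles for DHT, and grey bars for the middle 95% of 10000 random lists matched on mean expression. The androgen-induced list lies at −0.24 and −0.38 under DHT, and the hypoxia and glycolysis list lies above 0 in D226G cells and below 0 in M253K cells.

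A common set of genes separated both mutants from WT cells. Among 6444 names with a mean of at least 8 FPKM, 6 were at least 1.5-fold higher in both mutants under both hormone conditions: LBH, APLN, AGR2, S100P, BAMBI and IGFBP2. S100P was at 356 and 450 FPKM in D226G and M253K cells against 143 in WT cells under EtOH. IGFBP2 was at 89.99 and 99.8 against 56.7. In the same comparison 35 were lower, including UNC5B, TFF1, ST6GALNAC1, FXYD3, the metallothionein genes MT1F and MT1G, the carbonic anhydrase gene CA12, the tropomyosin gene TPM1 and B2M, the light chain of MHC class I. B2M was at 199 and 210 FPKM against 408 under EtOH, and at 340 and 264 against 518 under DHT. MT1F was at 11.2 and 13.3 against 32.2 under EtOH. The total of 41 was 105 for D226G alone and 89 for M253K alone. It was 220 from the EtOH groups alone and 89 from the DHT groups alone. All 4 differences of a gene use the same 2 WT groups. This rule, and the genes picked from it here, were chosen after the values were seen.

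**Figure D3:**
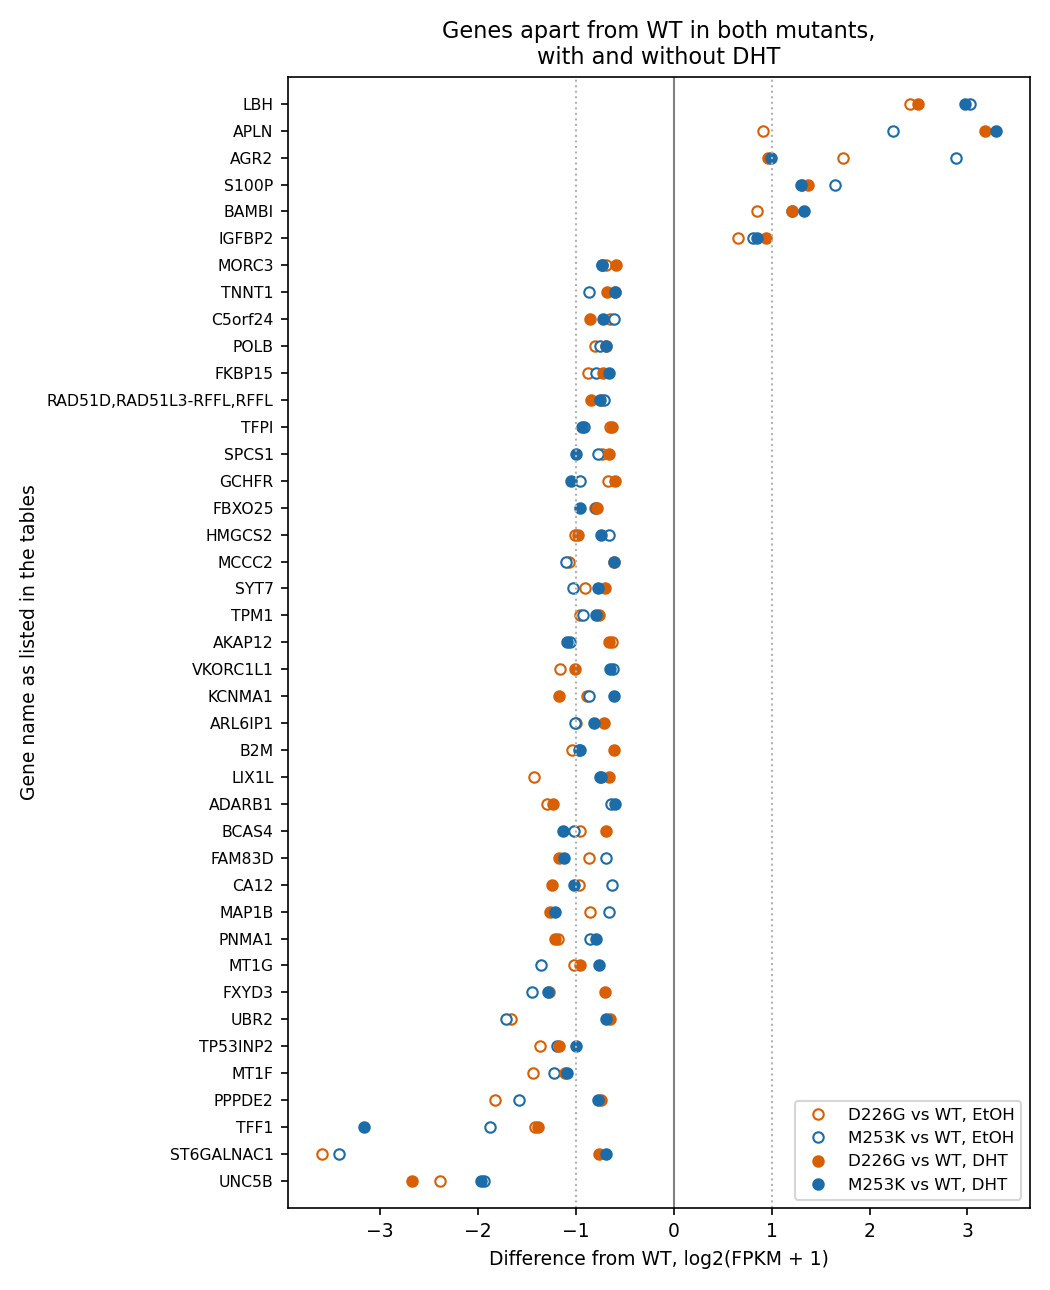
Log2(FPKM + 1) difference from WT for the 41 genes that lay at least 1.5-fold from WT in the same direction in both mutants and both hormone conditions, with open circles for EtOH and filled circles for DHT; dotted lines mark 2-fold. LBH and APLN lie farthest above WT on average and UNC5B farthest below.

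The mutants were also set against each other. Among names with a mean of at least 8 FPKM, 4 were at least 2-fold higher in M253K than in D226G cells under both hormone conditions and 9 were lower. The 4 were BCLAF1, ENAH, MMD and NAA38. GDF15, a stress-induced cytokine gene, was at 734 FPKM in M253K cells, 2568 in D226G cells and 1259 in WT cells under EtOH, and at 777, 2376 and 1400 under DHT. VEGFA (55.3 against 178 FPKM under EtOH), the neuronal enolase gene ENO2 (52.6 against 139), HMOX1 (9.79 against 21.1) and GADD45B (9.64 against 27.6) were likewise lower in M253K cells. The other 4 lower names were NMB, NBPF1, SNX25 and C19orf71. Apart from NAA38, MMD, NBPF1, NMB and C19orf71, genes of this paragraph fall outside the rule for named genes and were chosen after their values were seen. In all, 293 names differed at least 2-fold under EtOH and 214 under DHT. With small RNAs included the counts were 462 and 364, with a pseudocount of 0.1 they were 509 and 401, and with names on several rows at their largest value the DHT count was 352.

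The DHT response itself differed between forms by less than its own size for most androgen genes. KLK3 responded more in the mutants than in WT cells, by 0.40 (D226G) and 0.48 (M253K) on the log2 scale. TMPRSS2 responded less, by differences of −0.52 and −0.51. The FKBP5 response was 3.63 in WT, 3.19 in D226G and 2.53 in M253K cells. KLK2 differed by 0.13 and 0.51. The androgen-induced list had a median difference in response of −0.20 in D226G and −0.22 in M253K cells, both at percentile 0. The androgen-repressed list had medians of 0.43 (percentile 99.8) and 0.24 (percentile 96.6). The unfolded protein response list responded less in both, with a median of −0.25 in M253K cells (17 of 18 below 0, percentile 0) and −0.09 in D226G cells (11 of 18, percentile 0.16). In D226G cells the medians were also lower for G2/M (−0.24, percentile 0.02), G1/S (−0.15, percentile 1) and sterol and fatty acid synthesis (−0.06, percentile 1.13), and higher for ribosomal proteins (0.22, percentile 99.48). In M253K cells they were higher for hypoxia and glycolysis (0.30, percentile 99.98) and immediate early genes (0.28, percentile 99.95). The largest differences in response repeated in both mutants were in SMAGP, C19orf71, HIST1H2BL and ATP2B1. SMAGP was at 77.0 FPKM in the WT EtOH group and at 5.48 to 7.54 in every other group, and HIST1H2BL at 1.40 there and at 76.2 to 128 elsewhere. The difference in response of SMAGP and HIST1H2BL is thus that of 1 group. At a mean of at least 8 FPKM, 48 names were at least 2-fold higher in response in both mutants and 29 lower. Others of these also rest on the WT EtOH group, such as GYS1 (170 FPKM there, 19.9 to 26.8 elsewhere) and ATF6 (43.5, and 7.77 to 10.5). GYS1 and ATF6 were picked here after their values were seen. ATP2B1 was listed at 0 in the WT EtOH group and at 6.78 to 18.9 FPKM elsewhere. C19orf71 differed between the mutants. With DHT it went from 14.6 to 21.0 FPKM in D226G and from 0 to 0.699 in M253K cells, against 15.0 to 0.722 in WT cells. The names differing at least 2-fold in response numbered 434 for D226G (240 higher and 194 lower) and 389 for M253K (181 and 208). The counts were 780 and 736 with a pseudocount of 0.1 and 699 and 663 with small RNAs, and the M253K count was 257 with a filter at a mean of 5 FPKM.

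Across 11480 gene names, which are not independent replicates, the D226G and M253K differences from WT correlated with Pearson's r = 0.547 and Spearman's rho = 0.567 under EtOH, and with r = 0.440 and rho = 0.503 under DHT. Both mutants are set against the same WT group. Simulated unchanged groups gave r = 0.4997 and rho = 0.468 under EtOH and r = 0.5003 and rho = 0.473 under DHT. Their noise was drawn from the differences between the mutants, with the same spread in all 3 groups. That fixes the simulated r in advance. Under DHT the observed r lay below the simulated value and rho above it. The covariance differed from the simulated one by 0.0163 under EtOH and by −0.0189 under DHT. The noise holds any real differences between the mutants, which raise the simulated covariance. These values therefore do not decide whether the mutants share an effect. Shared 2-fold genes under EtOH numbered 48 higher and 114 lower, where independent lists would share 2.03 and 3.26. Under DHT they numbered 12 and 33, against 0.339 and 0.730. The WT values could not be split, so part of these excesses may come from the shared WT groups. Among names with a mean of at least 8 FPKM, the shared genes under EtOH were 32 higher and 53 lower. Of these, 18 and 29 were genes in which the WT EtOH group alone stood at least 2-fold from all other groups. Under DHT the shared genes were 5 and 10, with 0 and 2 in which the WT DHT group stood alone. Much of the EtOH excess thus rests on 1 group. Differences that share no group correlated with r = 0.259 between EtOH and DHT for D226G and r = 0.294 for M253K. Between the mutants, D226G under EtOH and M253K under DHT correlated with r = 0.263, and M253K under EtOH and D226G under DHT with r = 0.159. DHT responses of the 3 forms, which share no group either, correlated with r = 0.448 to 0.576.

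Some groups stood apart in single genes. Among names with a mean of at least 8 FPKM, 47 were at least 2-fold above or below all other groups in the WT EtOH group, 48 in the M253K EtOH group, 19 in the D226G EtOH group and 31 in the D226G DHT group. The WT and M253K DHT groups had 2 and 3. These include abundant genes listed near 0 in 1 group: the histone gene H2AFZ was at 0 in the D226G DHT group and at 175 to 327 FPKM in the others, and TOLLIP at 0 in the M253K EtOH group and at 29.5 to 34.2 in the others. Conversely, WDR38 was at 5141 FPKM in the D226G EtOH group and at most 3.02 elsewhere.

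**Figure D4:**
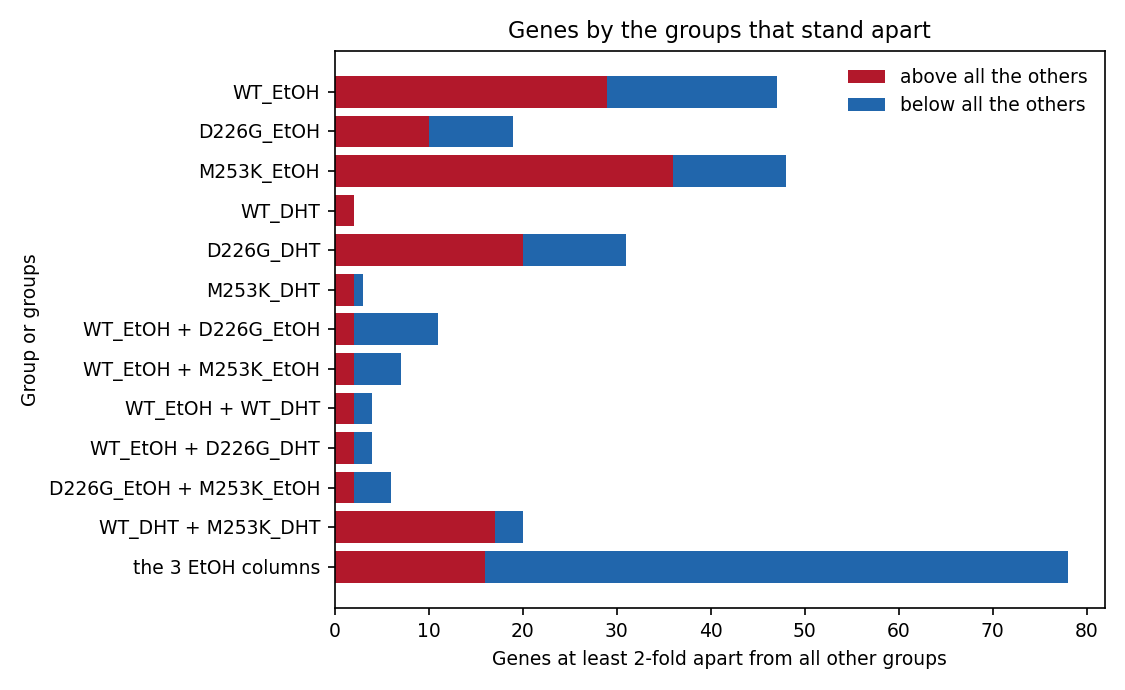
Number of genes with a mean of at least 8 FPKM that lie at least 2-fold above (red) or below (blue) all other groups, for each group, for pairs of groups with at least 4 such genes and for the 3 EtOH groups together. The EtOH groups together hold 78 such genes, and the WT and M253K DHT groups together hold 20.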

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

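The tests weighed below were all chosen after the results were seen. GDF15 and the hypoxia and glycolysis list lay on opposite sides of WT in the 2 mutants, with 1 value per group and no test of the difference. The log2 difference of GDF15 was 1.03 under EtOH and 0.76 under DHT in D226G cells, and −0.78 and −0.85 in M253K cells. The list medians were 0.32 and 0.38 in D226G cells and −0.46 and −0.20 in M253K cells. Opposite DHT responses were seen in 17 genes, at least 2-fold higher with DHT in one FOXA1 form and at least 2-fold lower in another, also untested. They include GSTM3, which was at 809 FPKM in the D226G DHT group and at 23.5 to 49.2 in the others, LAD1, STARD10, TOMM7 and IPW.

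D226G cells had more names at least 2-fold from WT under DHT than M253K cells, 129 against 30 at a mean of at least 8 FPKM. Depth does not account for it, since the ratio of the counts was 4.30 there and 2.43 over all names. The interquartile widths of the differences from WT were alike, at a ratio of 1.013 (M253K over D226G). Without replicates, noise may set both widths, so this ratio cannot exclude a general distance of D226G cells. The WT and M253K DHT groups together stood apart from the rest in 20 genes, against at most 11 for any other pair. Those genes differ between D226G and WT cells by construction. This count thus does not separate a processing output of its own for D226G from an effect of D226G alone. Names on several rows had differing values in 265 names for D226G and 0 for WT and M253K under EtOH. Under DHT the numbers were 0 for D226G, 340 for WT and 342 for M253K. This layout argues for a separate D226G output under both conditions. Comparisons with D226G may therefore cross outputs, while M253K against WT need not. How much of the D226G count comes from this was not tested, so an effect of D226G also stays open.

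The 41 genes apart from WT in both mutants, such as LBH and UNC5B, were also weighed. Reference groups taken from different forms for EtOH and DHT gave at most 10 such genes. Such mixed choices would be low with or without separate processing outputs, so these remain open. With the D226G groups as the reference there were 22, and with the M253K groups 7, so differences between single stable lines could account for part of the set. FOXA1 mRNA was at least 1.32 times the WT level in both mutants, so its amount may contribute too. With 1 line per form, these cannot be separated from the mutations.

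The androgen-induced list was lower in both mutants than in WT cells under DHT. Scaling does not account for it, as the medians were −0.27 and −0.40 after median-ratio scaling. Among 150 DHT-induced names outside the lists, the median difference in response from WT was −0.0545 in D226G and −0.03 in M253K cells, against −0.20 and −0.22 for the list. In level under DHT, 75 names outside the lists that were higher with DHT in all 3 forms were also lower in the mutants, with medians of −0.11 in D226G (45 below 0) and −0.19 in M253K cells (52 below 0). A weaker response of all induced genes is thus neither shown nor excluded.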

How the results depend on the processing

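For values without a test, a result was held to be unchanged when it moved by less than 1.5-fold and, except for counts, kept its direction. Counts were judged on their total alone, whichever direction held the majority. For list medians, a change of sign was called a reversal only for lists outside the percentile limits given above. Other medians that changed sign may therefore be among those that stayed. Of the alternatives for counts, 68 stayed within 1.5-fold and 25 did not. Of those for list medians, 426 stayed, 4 moved and 2 reversed, and of those for named genes 324 stayed and 38 moved, all with a pseudocount of 0.1. Median-ratio scaling shifted no median by more than −0.032. A pseudocount of 0.1 gave 934 (WT), 776 (D226G) and 865 (M253K) names for DHT against EtOH. It gave 554 and 627 for D226G and M253K against WT under EtOH, 483 and 318 under DHT, 509 and 401 between the mutants, and 780 and 736 for the response. A smaller pseudocount lets low values pass 2-fold. A filter at a mean of 5 FPKM, which leaves fewer names, gave 43 for M253K against WT under DHT and 257 for its response. It turned the interferon response list to −0.0023 (D226G) and −0.0413 (M253K) under EtOH, so that list has no stable direction there, and the cause was not tested. Small RNAs included gave 415 and 266 against WT under DHT, 462 and 364 between the mutants, and 699 and 663 for the response. Names on several rows at their largest value gave 384 for D226G against WT under DHT and 352 between the mutants. The majority direction also turned for M253K against WT under EtOH with small RNAs (278 higher and 279 lower), for its response with small RNAs (357 and 306) and for the D226G response with names on several rows (256 and 368). The totals of the first and last of these stayed within 1.5-fold, so both are among the 68. Genes repeated in the mutants numbered 105 without the M253K groups, 89 without the D226G groups, 220 from EtOH alone, 89 from DHT alone and 58 without the M253K DHT group (the 2 libraries with conflicting labels), as fewer conditions had to be met. No paired analysis was possible because each group has 1 value. For the same reason other scalings and filters on counts, other count models, thresholds on adjusted p, single libraries left out and gene set tests were not run.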

Other observations

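The metallothionein gene MT1G was lower in both mutants than in WT cells within each hormone condition, at 279 FPKM in D226G and 221 in M253K cells against 568 in WT cells under EtOH, and at 52.2 and 60.0 against 102 under DHT. MAP1B, a microtubule protein gene, was at 43.6 and 50.2 against 79.7 under EtOH. TP53INP2, an autophagy gene, was at 9.49 and 10.8 against 26.0, and PNMA1 at 21.6 and 27.3 against 50.4. These genes were chosen after their values were seen.

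The tables differ in how names with several rows are given. Such names had differing values only in the D226G column of the EtOH table (265 names) and in the WT (340) and M253K (342) columns of the DHT table. Values were missing for 229 names in the WT column and 224 in the M253K column under EtOH, and for 148 in the D226G column under DHT. Of the latter, 58 were listed under EtOH. In both hormone conditions the D226G column thus stood apart in layout from the WT and M253K columns. Every comparison with D226G may therefore also compare processing outputs.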
